A study of Mus musculus with 15 samples.

How the data were processed

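All quantities were computed from processed tables of the series and from the sample labels, and no reads were aligned here. The comparisons, gene lists, naming rules, main tests and alternatives were set before the data were examined, except where stated. The labels list 15 samples in 7 groups.

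Per the submitters' processing notes, Bowtie 0.12.9, TopHat, MACS2 and DESeq2 were used upstream with the mouse build mm9, and the role of each tool and its settings are not given in the sources used here. The RNA count values are integer read counts per gene and library, made by the authors and deposited unscaled. The chromatin tables give, per the file headers, a read count per feature for each pooled condition and the input. They also give log2 enrichment values that the authors deposited, and these were recomputed exactly as log2 of (reads + 16) over (scale × input reads + 16). The input scale in the promoter tables is 0.657 for untreated and 0.528 for irradiated FAIRE, and 0.706 and 0.712 for H3K27ac, and the deposited peak tables use the untreated scale for both conditions. The p-value and adjusted p-value columns come from the authors' deposited comparison of the RNA libraries and were used only for the comparison with their table. The peak score column was deposited by the authors and was used only to rank peaks for an alternative. The columns with DMSO in their header were taken as the irradiated conditions, because the labels' protocol gives DMSO-containing medium to irradiated cells. The number of columns with values per sample or condition that were not used is 8.

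RNA counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr with default settings, TMM scaling, glmQLFit with default settings and the quasi-likelihood F test, with Benjamini-Hochberg adjustment (BH) over the 14925 genes tested and a threshold of 0.05. CPM values used TMM-scaled library sizes, except those of Lars2 and of all sensory receptor genes together, which used library totals. The log2 CPM values for the set tests and the principal components used a prior count of 2. The standard error of a log2 fold change is its size divided by the square root of F. The common biological coefficient of variation was 0.237. Symbols are those of the files, of which 93.5% were found in a RefSeq name table, and current symbols were taken from that table. The fixed gene lists, 26 in number, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 with BH over the lists. The alternatives were an estimated correlation and fry, both in limma. Genes were named by rule: the 10 highest and 10 lowest called genes with a mean of at least 5 CPM over the libraries and no overlap in CPM between the groups, and up to 4 called members per list by smallest p, or 2 members where none was called. Per assay and direction, 5 promoters of tested genes and 3 peaks of at least 200 bp were named, from the upper 50% by mean enrichment. Coordinates are given as 1-based. Some single genes picked by these rules are not reported here.

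Chromatin tables were analysed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The difference is the irradiated minus the untreated log2 enrichment, and a gain or loss is a difference of at least 1 in size. Intervals of medians are 95% binomial intervals over features and do not measure the spread between samples. Read ratios are scaled by the pools' depth, and their exact conditional binomial intervals cover counting error only. For each list, 10000 random lists of the same size were drawn from the promoters of tested genes within 10 classes of mean enrichment, and the list's median was placed among theirs. Peaks were intersected with bedtools 2.31.1 at a minimum of 1 bp. Figures were drawn with matplotlib 3.10.9.

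The edgeR steps were tested on simulated data drawn from a negative binomial distribution with the means, library sizes and dispersions of the real libraries, in which 200 genes were changed. Of 111 genes changed by a log2 of 1, 82 were recovered (73.9%), of 89 changed by a log2 of 2, 88 were recovered (98.9%), and 10 of the other genes were called among 14306 run. Of 200 random lists of promoters with no change added 5.5% lay outside the central 95%, and a list raised by 0.5 lay at percentile 100.

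Alternatives tried for RNA were DESeq2 1.42.0 (Wald test), its size factors in the edgeR fit, library totals alone, no low-count filter and a filter of at least 1 CPM in 3 libraries. Others were the replicate number as a block, a log2 fold change of at least 1, and the fit without each library in turn. For chromatin they were centring, quantile normalization, a threshold of 0.58, the features in the upper 50% by mean enrichment, and an overlap of 50% of the shorter peak or the upper 50% of peaks by score. The use of each pool's own input scale at peaks, 1 read added in place of 16, and 7 further gene sets by symbol pattern were added after the data were seen. A change of RNA with gene length was not analysed here, because no gene annotation was used.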

Results

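The series asked how chromatin and transcripts of mouse fibroblasts respond to ultraviolet damage. NIH3T3 cells, an established line of mouse embryonic fibroblasts, were left untreated or were exposed to 80 J/m2 of UV-C light of 254 nm, which forms lesions between neighbouring pyrimidines in DNA, and were sampled 6 h later. Open chromatin was measured by FAIRE-seq, in which DNA poorly crosslinked to protein is recovered from the aqueous phase of a phenol extraction, with 2 untreated and 2 irradiated samples. Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was measured by ChIP-seq with 2 samples per condition, and 1 input DNA sample served both assays. Transcripts were measured by RNA-seq with 3 untreated and 3 irradiated libraries. The RNA libraries held 14211528 to 22032701 counts over genes, and 14925 of the 19069 genes in the files had enough counts to test. The chromatin tables hold reads pooled over the 2 samples of a condition, so their values have no spread between replicates and no test. The irradiated cells were washed and received fresh medium containing DMSO after exposure. The labels do not say whether the untreated cells were handled alike. Each comparison is therefore of cells that were irradiated, re-fed and given DMSO with untreated ones.

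Irradiated cells held far more mRNA of the AP-1 transcription factors and of other fast-responding genes, and far less histone mRNA. Of the 14925 genes tested, 1149 were higher and 1854 were lower after UV at an adjusted p below 0.05 in edgeR's quasi-likelihood test, and 270 and 801 of these differed at least 2-fold. Fos, which encodes an AP-1 subunit, rose from 6.75 ± 0.666 to 138 ± 17.5 CPM (mean ± SD, n = 3 per group), a log2 fold change of 4.35 ± 0.21 (SE, adjusted p = 1.17e-09). Its paralog Fosb rose by a log2 fold change of 5.29 ± 0.29 (adjusted p = 3.67e-09), from 1.26 ± 0.670 to 50.6 ± 10.0 CPM. Among genes with at least 5 CPM on average and no overlap between the groups, the 10 highest also held 1810011O10Rik (now named Tcim, log2 fold change 5.34), Nppb, which encodes a natriuretic peptide (5.01), and Pmaip1, which encodes the pro-apoptotic BH3-only protein Noxa (4.19). The others were 1700056E22Rik (3.94), the cytokine gene Lif (3.80), the stress gene Gadd45a (3.72), the stress-induced transcription factor gene Atf3 (3.58) and the antiproliferative gene Btg2 (3.10). The 10 lowest genes held 5 histone genes, led by Hist1h3g (log2 fold change −3.19 ± 0.23, adjusted p = 8.42e-08), Hist1h1d (−2.90) and Hist1h1b (−2.83). The other 5 were the ephrin gene Efna4 (−2.79), the pseudokinase gene Trib2 (−2.57), the Polycomb gene Cbx2 (−2.54), the growth-arrest gene Gas1 (−2.52) and the F-box gene Fbxo31 (−2.49). Gas1 was at 424 ± 160 CPM in untreated and 74.1 ± 19.3 CPM in irradiated cells. The p-values measure only the spread between these libraries, as the labels do not say whether they came from separate cultures. By a chi-square over genes per degree of freedom, irradiated replicates 2 and 3 were closest (4.62), against 14.15 to 44.4 for other pairs within a group. Replicate 1 was the farthest library in both groups. Irradiated replicate 1 lay at 44.4 and 42.34 from irradiated replicates 2 and 3. Untreated replicate 1 lay at 35.48 and 33.01 from untreated replicates 2 and 3, which were 14.15 apart. The 3 irradiated and the 3 untreated libraries did not overlap in CPM for 33.9% of all tested genes, against 10% for a gene with no difference. Scaled by library totals alone, the median of all tested genes moved from −0.01 to −0.24 and the calls split into 905 higher and 3739 lower, 19.5% higher against 38.3%, so that the balance of rises and falls depended on the scaling. Irradiated replicate 1 also stood apart in genes detected, with 17607 against 18350 to 18787 in the other libraries. Without it 1188 genes were higher and 2849 lower. By library totals without TMM scaling, it also held 5582 CPM of Lars2, against 1257 and 1617 in the other irradiated libraries. The untreated libraries held 520 to 943 CPM on that scale. Lars2 was called higher after UV in the TMM-scaled fit (log2 fold change 2.45 ± 0.46, adjusted p = 0.000884). What raised the Lars2 reads in irradiated replicate 1 was not tested. Without untreated replicate 1 or 2, 1796 or 1941 genes were higher, without untreated replicate 2, 1168 were lower, and without irradiated replicate 3, 585 were higher and 1139 lower.

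**Figure D1:**
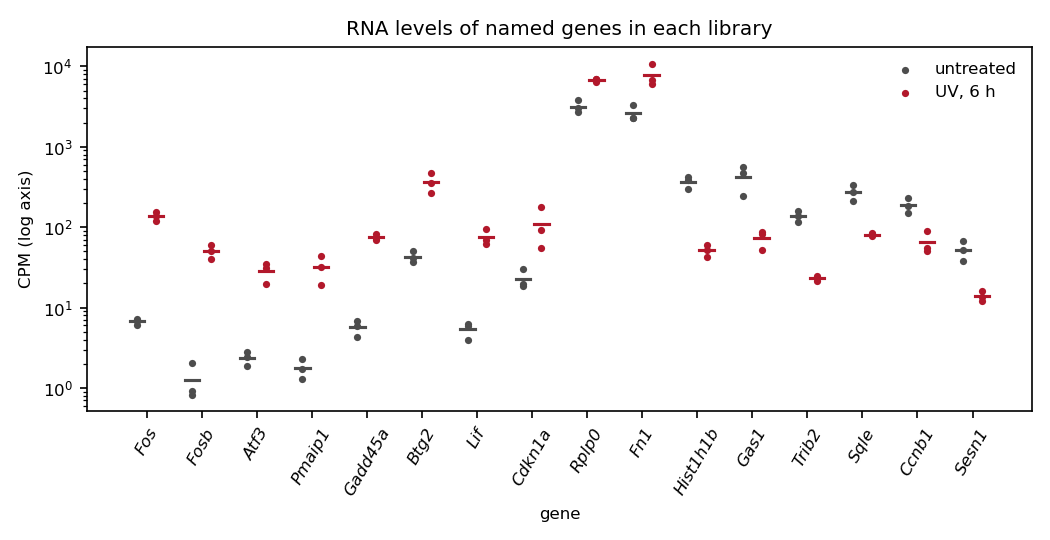
CPM (log axis) of 16 named genes in the 3 untreated (grey) and 3 irradiated (red) RNA libraries, where each point is a library and each bar a group mean. Fos lay between 6.01 and 7.31 CPM in untreated and between 120 and 155 CPM in irradiated libraries, and Trib2, Sqle and Hist1h1b lay lower in all 3 irradiated libraries than in any untreated one.

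Immediate early and AP-1 genes formed the fixed list with the highest median. Of its 32 tested members, 22 rose, 2 fell and 8 did not pass the test, with 24 and 2 adjusted over the list alone, and the median log2 fold change was 1.35. Besides Fos, Fosb and Atf3, Ier3, which encodes an early response protein, rose from 40.5 ± 3.49 to 282 ± 63.5 CPM (log2 fold change 2.80 ± 0.22, adjusted p = 2.13e-07). The list stood above the other genes in the camera test with a preset correlation (adjusted p = 1.48e-12), but not with an estimated correlation (adjusted p = 0.791). Of 24 NF-kB and inflammatory genes 6 rose and 2 fell, also adjusted over the list alone. Lif, the chemokine gene Ccl7 (log2 fold change 2.09) and the cyclooxygenase gene Ptgs2 (1.85) were among the rises and the adhesion gene Vcam1 (−0.99) among the falls. With library totals alone, which lowered the tested genes as a whole, 3 rose and 4 fell, so the balance of calls depended on the scaling. Without irradiated replicate 1 9 rose and 4 fell. The median of 0.27 was 0.06 with library totals alone and 0.12, 0.15 and 0.09 without untreated replicate 1, irradiated replicate 2 and irradiated replicate 3, but 0.45, 0.54 and 0.45 without untreated replicate 2, untreated replicate 3 and irradiated replicate 1. The call of Ptgs2 was lost without untreated replicate 2 (adjusted p = 0.0709), that of Ccl7 with library totals alone (adjusted p = 0.0572), and that of Vcam1 without untreated replicate 2 or 3 (adjusted p = 0.102 and 0.0587). The list did not pass the camera set test (adjusted p = 0.161), but did without irradiated replicate 1 (adjusted p = 0.0443) and with the replicate number as a block (adjusted p = 0.0329), and with an estimated correlation the adjusted p was 0.99. Of 26 targets of ATF4 and the unfolded protein response 7 rose and 1 fell, also adjusted over the list alone. Ppp1r15a, which encodes a phosphatase subunit acting on eIF2alpha, rose by 2.14, the transcription regulator gene Nupr1 by 2.09, the glutathione-degrading enzyme gene Chac1 by 1.87 and the chaperone gene Dnajb9 by 1.38 on the log2 scale. This list passed the preset test (adjusted p = 0.000556) and not the test with an estimated correlation (adjusted p = 0.99), and its median of 0.37 came to 0.06 without irradiated replicate 1 and to 0.12 with library totals alone, against 0.57 without untreated replicate 1. Of 21 interferon response genes none rose and 1 fell, which was Irf1 (log2 fold change −0.80 ± 0.22, adjusted p = 0.0139). Its call was lost without untreated replicate 2 or 3 (adjusted p = 0.262 and 0.165), and the list, with a median of −0.04 and a mean of 0.01, did not pass the camera set test (adjusted p = 0.966). The median was 0.17, 0.22 and 0.27 without untreated replicate 2, untreated replicate 3 and irradiated replicate 1. It was −0.12 and −0.24 without irradiated replicates 2 and 3, and −0.25 with library totals alone, where 2 genes fell.

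Targets of the tumour suppressor p53 went both ways. Of 30 tested targets 8 rose, 4 fell and 18 did not pass the test, with 8 and 6 adjusted over the list alone. Of all tested genes 7.70% rose and 12.4% fell, so rises were more frequent among the targets, and falls were about as frequent. The list's median log2 fold change was −0.01 and its mean 0.28, with the camera test pointing up (adjusted p = 0.579). Pmaip1 rose from 1.77 ± 0.491 to 31.9 ± 12.5 CPM. The kinase gene Plk3 rose by 2.74 ± 0.20 (adjusted p = 8.42e-08) and Btg2 by 3.10 ± 0.25 on the log2 scale. Sesn1, which encodes a stress-induced regulator of mTORC1, fell by 1.91 ± 0.21 (adjusted p = 7.37e-06). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose from 22.7 ± 6.23 to 109 ± 63.9 CPM (log2 fold change 2.26 ± 0.32, adjusted p = 6.96e-05). Of 32 nucleotide excision repair genes, whose products remove UV lesions, 4 rose and 7 fell, also adjusted over the list alone. Of the repair genes 2 rose and 9 fell with library totals alone. The median was 0.05 (−0.18 with library totals alone, −0.09 without irradiated replicate 1, and 0.09 to 0.23 without each other library) and the mean −0.07, with the camera test pointing down (adjusted p = 0.966). Rpa2, which encodes a subunit of the single-strand binding protein RPA, fell by 1.67, the TFIIH subunit genes Gtf2h3 and Ercc2 fell by 1.05 and 1.01, and the damage sensor gene Xpc fell by 0.78 on the log2 scale. Of 30 checkpoint signalling genes none rose and 8 fell, also adjusted over the list alone (set test adjusted p = 0.258, and adjusted p = 0.99 with an estimated correlation), among them Wee1 (−1.71), Cdc25b (−1.24), Cdc25a (−1.24) and the checkpoint clamp loader gene Rad17 (−1.23). Of these genes 14 fell with library totals alone, at a median of −0.33 (adjusted p = 0.0505). Its median of −0.08 was −0.30 without irradiated replicate 1, where the list passed the set test (adjusted p = 0.00496). It was 0.13, 0.03 and 0.05 without untreated replicate 1, untreated replicate 2 and irradiated replicate 2. The median of all tested genes in these fits was 0.12, 0.03 and −0.07. Of 24 apoptosis regulators 2 rose and 10 fell, with 2 and 13 adjusted over the list alone, and the pro-apoptotic genes Bid (−2.42), Casp6 (−1.79) and Bcl2l11 (−1.15) and the anti-apoptotic gene Bcl2l1 (−1.40) were among the falls. The apoptosis list passed the preset test (adjusted p = 0.0416), not the test with an estimated correlation (adjusted p = 0.99) and not with library totals alone (adjusted p = 0.0684). Without untreated replicate 2 or irradiated replicate 2 its adjusted p was 0.134 or 0.162. Without irradiated replicate 1 and with library totals alone the counts of p53 targets were 6 higher and 10 lower, at medians of −0.29 and −0.28. Without untreated replicate 1 or 2 or irradiated replicate 2 or 3 the p53 median was 0.16, 0.05, 0.07 and 0.03.

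Replication-dependent histone genes fell and ribosomal protein genes rose in nearly every tested member. Of 27 histone genes 25 fell and none rose, with 26 falling adjusted over the list alone, at a median log2 fold change of −1.67. The linker histone gene Hist1h1b fell from 368 ± 61.5 to 51.8 ± 8.50 CPM, and Hist1h1d, Hist1h2bc and Hist1h4i fell by 2.90, 2.52 and 2.40 on the log2 scale. The list passed the preset test (adjusted p = 2.12e-24) and not the test with an estimated correlation (adjusted p = 0.369). Of 49 ribosomal protein genes 47 rose and none fell, also adjusted over the list alone, at a median of 0.99. Rplp0, which encodes a stalk protein, rose from 3167 ± 546 to 6789 ± 284 CPM (log2 fold change 1.10 ± 0.20, adjusted p = 0.000584). Rpl31, Rplp1 and Rps2 rose by 1.12, 1.15 and 1.05. The ribosomal list passed the preset test (adjusted p = 6.11e-28) and not the test with an estimated correlation (adjusted p = 0.791). All ribosomal protein genes together took 6.68% to 8.56% of the counts in untreated and 10.7% to 14.6% in irradiated libraries, and histone genes took 0.417% to 0.432% and 0.121% to 0.153%. Both families hold near-identical copies and, for ribosomal proteins, many pseudogenes, so the values of single members are uncertain. Replication-dependent histone mRNAs mostly lack a poly(A) tail, and the labels do not state whether the libraries were selected for poly(A), so it is not known which part of the histone transcripts was counted. Among 30 genes of G1/S transition and DNA replication none rose and 6 fell, also adjusted over the list alone (set test adjusted p = 0.55). The falls included the histone mRNA binding protein gene Slbp (−1.35), Cdca7 (−1.84), the origin recognition gene Orc1 (−1.30) and the cyclin gene Ccne1 (−1.26). Among 30 genes of G2/M and mitosis none rose and 7 fell, also adjusted over the list alone (set test adjusted p = 0.0623). The falls included Cdk1 (−1.55), Ccnb1 (−1.53), the mitotic kinase gene Plk1 (−1.12) and Sgol1 (−0.91). Without irradiated replicate 1, 10 of the G1/S and 17 of the G2/M genes fell and both lists passed the camera set test (adjusted p = 0.0158 and 3.88e-05). These passes were at the preset correlation. With an estimated correlation of 0.839 and 0.971 in the fit of all libraries the adjusted p was 0.99 for both lists. Falls numbered 9 and 14 with library totals alone. The G2/M list also passed without untreated replicate 3 (adjusted p = 0.00353), with library totals alone (adjusted p = 0.0344), with the replicate number as a block (adjusted p = 0.018) and without a low-count filter (adjusted p = 0.0423). Its median of −0.27 was 0.05 without untreated replicate 1 (adjusted p = 0.598). The G1/S median of −0.05 was 0.23, 0.06, 0.12 and 0.07 without untreated replicate 1, untreated replicate 2, irradiated replicate 2 and irradiated replicate 3, but −0.27 without irradiated replicate 1 and −0.30 with library totals alone. The G2/M median was −0.59 and −0.53 in these 2 fits. The direction of the G1/S list thus depended on the libraries included. Without untreated replicate 1, where the G2/M median was 0.05, the median of all tested genes was 0.12. In each fit without a library the G2/M median lay below that of all tested genes. The gap was smallest without irradiated replicate 2 (−0.10 against −0.07).

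Of 37 matrix genes 4 rose and none fell, also adjusted over the list alone, against 6 and 4 without irradiated replicate 1 and 5 and 2 with library totals alone. The fibronectin gene Fn1 rose from 2639 ± 614 to 7898 ± 2564 CPM (log2 fold change 1.58 ± 0.24, adjusted p = 0.000144) and the lysyl oxidase gene Loxl2 rose by 1.70, Col12a1 by 0.93 and Fbln5 by 0.88. The matrix list's median of 0.42 (adjusted p = 0.00686, and adjusted p = 0.99 with an estimated correlation) came to 0.00 without irradiated replicate 1 (adjusted p = 0.324) and 0.14 with library totals alone, and its adjusted p was 0.0627 without untreated replicate 3. Of 18 matrix proteases and their inhibitors 2 rose and 4 fell, with 4 and 4 adjusted over the list alone (set test adjusted p = 0.569). The inhibitor gene Timp1 was at 1.15 and the protease genes Mmp11, Adamts1 and Adamts5 at −1.50, −1.30 and −0.71. Of the proteases and inhibitors 4 rose and 5 fell without irradiated replicate 1, and the median of 0.32 was 0.10 there and 0.08 with library totals alone. Of 25 NRF2 targets 6 rose and 3 fell, with 8 and 3 adjusted over the list alone, with Gpx1 at 1.27, Ftl1 at 1.15, Nfe2l2, which encodes NRF2 itself, at −0.99 and Gclc at −1.56. The NRF2 list passed the preset test (adjusted p = 0.0416, and adjusted p = 0.99 with an estimated correlation), but not without irradiated replicate 1 (adjusted p = 0.466) or untreated replicate 3 (adjusted p = 0.218). Its median of 0.31 was 0.04 without irradiated replicate 1 and 0.07 with library totals alone, against 0.56 without untreated replicate 1. Of 19 heat shock genes 1 rose (Hsph1, 0.91) and 3 fell (Hspa1b, −1.11, Hsf2, −0.80, and Hspb8, −0.58), with 2 and 3 adjusted over the list alone. The heat shock median was 0.01 (−0.23 with library totals alone, −0.15 without irradiated replicate 1, and 0.02 to 0.20 without each other library) and the mean −0.05, with the camera test pointing down (adjusted p = 0.966). Of 20 genes of the cholesterol list none rose and 4 fell, also adjusted over the list alone (set test adjusted p = 0.0631, and adjusted p = 0.99 with an estimated correlation). Of the list 1 rose and 7 fell without irradiated replicate 1, and with library totals alone none rose and 7 fell at a median of −0.47. Among the falls were Sc4mol (−2.05) and the squalene epoxidase gene Sqle (−1.74). Its median of −0.25 was −0.30 without untreated replicate 1, where the list passed the set test (adjusted p = 0.000385), as it did without a low-count filter (adjusted p = 0.0423). Without untreated replicate 2 the median was 0.05 (adjusted p = 0.638) and without untreated replicate 3 −0.08 (adjusted p = 0.128). Of 16 clock genes none rose and 4 fell, also adjusted over the list alone, which were Arntl (−1.35), Cry2 (−1.10), Nfil3 (−0.97) and Bhlhe40 (−0.66). Clock genes that fell numbered 9 without irradiated replicate 1 and 6 with library totals alone, and the median of −0.44 was −0.86 and −0.68. It was −0.18 without untreated replicate 1. The clock list passed the preset test (adjusted p = 0.0416), not with an estimated correlation (adjusted p = 0.99) and not with library totals alone (adjusted p = 0.117). Leaving out untreated replicate 1, irradiated replicate 2 or irradiated replicate 3 gave adjusted p values of 0.0627, 0.162 and 0.0794. Of 26 Hippo and TGF-beta targets 2 rose and 8 fell, with 3 and 11 adjusted over the list alone, with Smad6 at −2.04, Id3 falling from 124 ± 25.7 to 30.9 ± 8.32 CPM, Amotl2 at −1.23 and Ankrd1 at −1.23. Of these targets 2 rose and 13 fell without irradiated replicate 1, and with library totals alone 1 rose and 14 fell, at medians of −0.58 and −0.68 against −0.44. The median was −0.10 without untreated replicate 1. That list passed the preset test (adjusted p = 0.0296) and not with an estimated correlation (adjusted p = 0.99) or with library totals alone (adjusted p = 0.0552). Nor did it pass without untreated replicate 1, irradiated replicate 2 or irradiated replicate 3 (adjusted p = 0.183, 0.208 and 0.052). Of 31 chromatin regulators 3 rose and 4 fell, also adjusted over the list alone (set test adjusted p = 0.65). Among them were Kdm6b at 0.94, Hdac1 at 0.67, Kdm5b at −0.70 and Kat5 at −0.60, and the median was 0.05, −0.19 with library totals alone, where 2 rose and 9 fell, and −0.03 without irradiated replicate 1, where 2 rose and 5 fell. It was 0.09 to 0.24 without each other library. Of 15 genes often used as controls 6 rose and 1 fell, also adjusted over the list alone, with Polr2a at 0.89, B2m at 0.87, Eef1a1 at 0.66 and Tbp at −1.19. Of the controls 2 rose and 1 fell without irradiated replicate 1, and with library totals alone 4 rose and 3 fell, at medians of 0.35 and 0.21 against 0.44. The control list passed the preset test (adjusted p = 0.0143), not with an estimated correlation (adjusted p = 0.99), and not without irradiated replicate 1 (adjusted p = 0.118) or untreated replicate 3 (adjusted p = 0.0666). Markers of epithelial (6 genes tested), endothelial (8), muscle (7) and adipocyte cells (8) held no called gene (set test adjusted p = 0.966, 0.948, 0.454 and 0.966), the adipocyte markers having a median of 0.01 and a mean of −0.03. Of 8 leukocyte markers only Cd68, which fibroblasts also transcribe, rose (set test adjusted p = 0.535), from 4.03 ± 0.0934 to 10.6 ± 0.701 CPM (log2 fold change 1.39). The mean CPM of the other marker genes named by the rule was at most 7.32 (Tnnt2, irradiated). Acta1 and Tnnt2 passed the test without untreated replicate 1, with log2 fold changes of 2.20 and 2.44, as did Tnnt2 without irradiated replicate 3 (1.17) and with the replicate number as a block (0.75, adjusted p = 0.0282).

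The calls of 17 of the 101 named genes were lost in at least 1 of the other fits. Hspb8 was not called without untreated replicate 1 or 2 or irradiated replicate 2 or 3 (adjusted p = 0.115, 0.104, 0.0979 and 0.277), nor with DESeq2 size factors (adjusted p = 0.0537). Hspa1b was lost without untreated replicate 2 (adjusted p = 0.0524). Bhlhe40 was lost without untreated replicate 1, 2 or 3 (adjusted p = 0.428, 0.102 and 0.076) and without irradiated replicate 2 or 3 (adjusted p = 0.127 and 0.115), and in DESeq2 (adjusted p = 0.0598). Nfil3 was lost without untreated replicate 2 or 3 (adjusted p = 0.129 and 0.0788). Adamts5 was lost without untreated replicate 2 or irradiated replicate 2 or 3 (adjusted p = 0.0533, 0.0746 and 0.147). Without irradiated replicate 3 the calls of Col12a1 (adjusted p = 0.0632), Kdm5b (0.0823), Hdac1 (0.132), Kat5 (0.199), B2m (0.0809) and Eef1a1 (0.198) were lost. Eef1a1 was also lost without irradiated replicate 1 (adjusted p = 0.11) and with library totals alone (0.101). Other losses were Kdm6b without irradiated replicate 1, without untreated replicate 2 and with library totals alone (0.0598, 0.0631 and 0.0761), Kdm5b without untreated replicate 2 (0.0601) and Kat5 without irradiated replicate 2 (0.0541). In the fry set test, which does not compare a list with other genes, the ATF4, NRF2, matrix, clock, Hippo and control lists did not pass (adjusted p = 0.302, 0.442, 0.427, 0.0897, 0.302 and 0.302). The immediate early, apoptosis, histone and ribosomal lists did (adjusted p = 0.0129, 0.0244, 0.000398 and 0.0155).

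**Figure D2:**
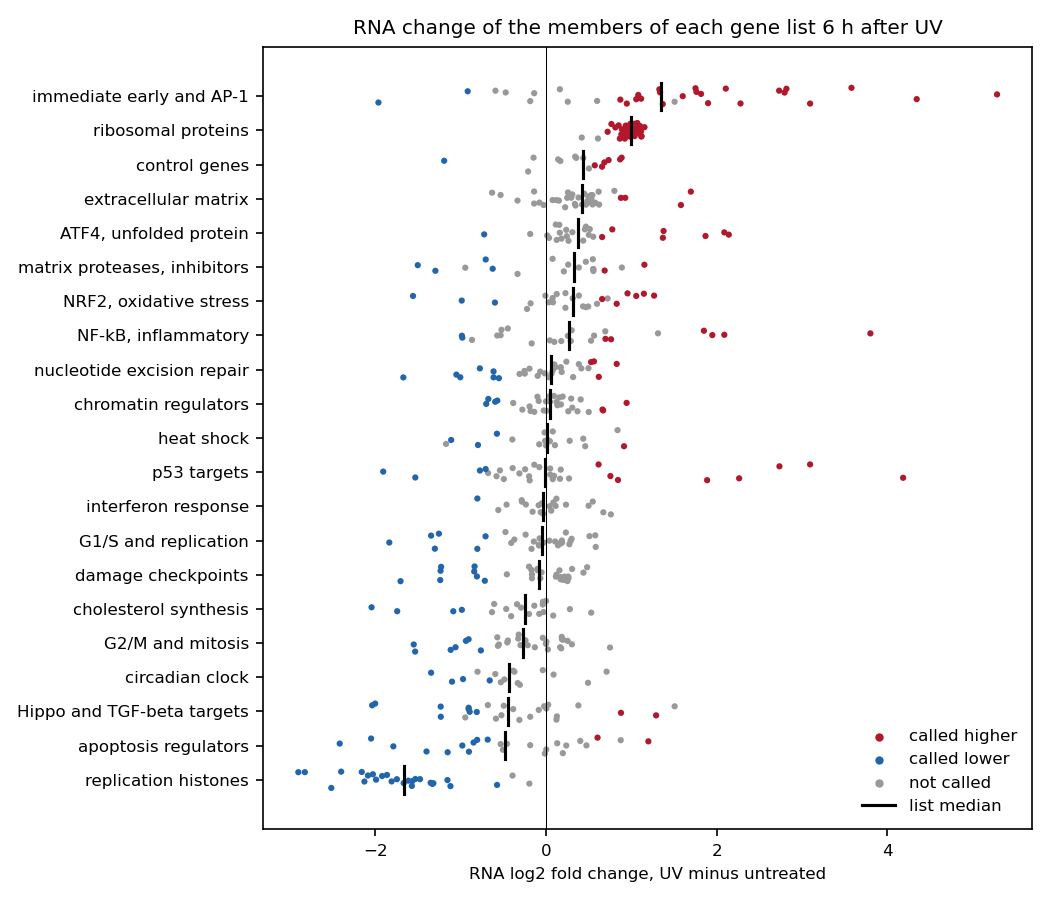
RNA log2 fold change (UV minus untreated) of each tested member of 21 fixed gene lists, where each point is a gene, coloured by whether it was called higher, called lower or not called, and each black bar is the list's median. Medians ran from −1.67 for replication histones to 1.35 for immediate early and AP-1 genes, and ribosomal protein genes lay close together around 0.99.

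In the authors' deposited table of their own comparison, 2068 genes were listed, 832 higher and 1236 lower after UV. Their adjusted p values reached 0.0999, beyond the threshold of 0.05 used here. Of the 1633 genes with an adjusted p below 0.05 in the authors' deposited table, 1625 were also called here with the same sign. Of the 3003 genes called here at an adjusted p below 0.05, 2034 were in that wider list at any adjusted p and 969 were not.

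Promoters of p53 targets and immediate early genes gained H3K27ac, and promoters of cholesterol synthesis genes lost it. Over 21881 promoter windows of 1000 bp, the median difference in log2 enrichment, irradiated minus untreated, was −0.01 (95% binomial interval of the median −0.03 to −0.01), with 520 gains and 750 losses of at least 1. It was 0.02 with quantile normalization and 0.04 for promoters in the upper 50% by enrichment, and with 1 read added in place of 16 there were 1381 gains and 3479 losses. The median promoter held 49 H3K27ac reads in the untreated and 38 in the irradiated pool, and all intervals on reads cover counting error only. The p53 targets had a median difference of 1.29, above all of 10000 random lists matched on enrichment (central 95% −0.07 to 0.39), and 18 of the 30 promoters gained at least 1 while none lost as much. Among them, Pmaip1 went from 32 to 252 reads (log2 enrichment 0.74 to 3.22), Btg2 from 362 to 1369 reads (2.80 to 4.67) and Dcxr, which encodes a carbonyl reductase, from 69 to 530 reads (1.37 to 4.04). Bbc3, which encodes the pro-apoptotic protein Puma, went from 356 to 1680 reads (3.41 to 5.59). Of these 18 genes 6 were called higher in RNA and 12 were not called, with Bbc3 RNA at a log2 fold change of 0.27 (adjusted p = 0.619). The immediate early genes had a median difference of 0.89, also above all 10000 random lists (0.04 to 0.43), with 15 gains of at least 1 and no such loss. Fosb went from 107 to 411 and Atf3 from 164 to 419 reads. Medians of the ATF4 list (0.44), the NF-kB list (0.41) and the Hippo and TGF-beta list (0.44) also lay above the central 95% of random lists. The cholesterol list had a median of −0.73, below all 10000 random lists (−0.31 to 0.29), and 7 of 20 promoters lost at least 1. Among them Fdps, which encodes an enzyme of sterol synthesis, went from 477 to 59 reads, and its RNA did not pass the test (adjusted p = 0.180). The extracellular matrix (−0.34), matrix protease (−0.33), interferon (−0.45), G2/M (−0.27) and NRF2 lists (−0.26) lay below the central 95% of random lists as well, and none of the 5 marker lists lay outside it. The percentiles of the 26 lists in the 2 assays were not adjusted for their number. The highest gains chosen by size also held Aebp2, a Polycomb cofactor gene (251 to 1775 reads), A630007B06Rik (137 to 743) and Atg9b (36 to 233). Strong losses were also found at Aqp5 (145 to 12), the Polycomb gene Cbx6 (668 to 104) and Galnt9 (255 to 32).

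FAIRE enrichment at promoters was lower in the irradiated pool at 68.0% of promoters and higher at 29.9%, and the p53 target Cdkn1a had the only gain of at least 1. The median difference over 21881 promoters was −0.17 (95% binomial interval −0.18 to −0.17), with 1 gain and 229 losses of at least 1, and among promoters in the upper 50% by enrichment the median was −0.40. With quantile normalization, which brings both columns to the same distribution, the median was 0.00 with 12 gains and 27 losses. That setting removes a shared shift by construction, so the general fall rests on the input scale and this setting cannot test it. Centred on their median the differences held 10 gains and 76 losses, and with 1 read added in place of 16 they held 638 and 1279 around a median of −0.25. The median promoter held 24 FAIRE reads in the untreated and 18 in the irradiated pool. The Cdkn1a promoter went from 26 to 82 reads and from 0.08 to 1.49 in log2 enrichment, a depth-scaled read ratio of 3.93. The next highest differences were at the Notch ligand gene Dll3 (14 to 36 reads), Marcksl1 (93 to 159), Bbc3 (41 to 76) and the receptor gene Epha2 (26 to 51). The lowest were at the retrotransposon-derived gene Rtl1 (71 to 6 reads), Gas1 (139 to 30), Cbx6 (114 to 24), the H4K20 methyltransferase gene Setd8 (178 to 44) and the Wnt pathway gene Dvl1 (60 to 8). RNA of Cdkn1a and Marcksl1 (log2 fold change 1.69) rose, that of Rtl1 (−1.53), Gas1 (−2.52) and Setd8 (−0.54) fell, and that of Dll3, Bbc3, Epha2, Cbx6 and Dvl1 did not pass the test. Promoters of p53 targets (median −0.15), immediate early genes (−0.18), NF-kB genes (−0.12) and Hippo and TGF-beta targets (−0.28) had medians above the central 95% of matched random lists, as did those of the muscle markers (0.21), which hold few reads. Promoters of cholesterol genes (−0.71), heat shock genes (−0.69), replication histones (−0.60), control genes (−0.62) and matrix genes (−0.51) had medians below it. With quantile normalization the medians of the p53, immediate early, NF-kB and Hippo lists were 0.31, 0.26, 0.22 and 0.13. Those of the cholesterol, heat shock, histone, control and matrix lists were −0.20, −0.19, −0.22, −0.06 and −0.27. That setting removes a shift shared by all promoters. The signs of the p53, immediate early, NF-kB and Hippo medians depended on whether that shift was kept.

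**Figure D3:**
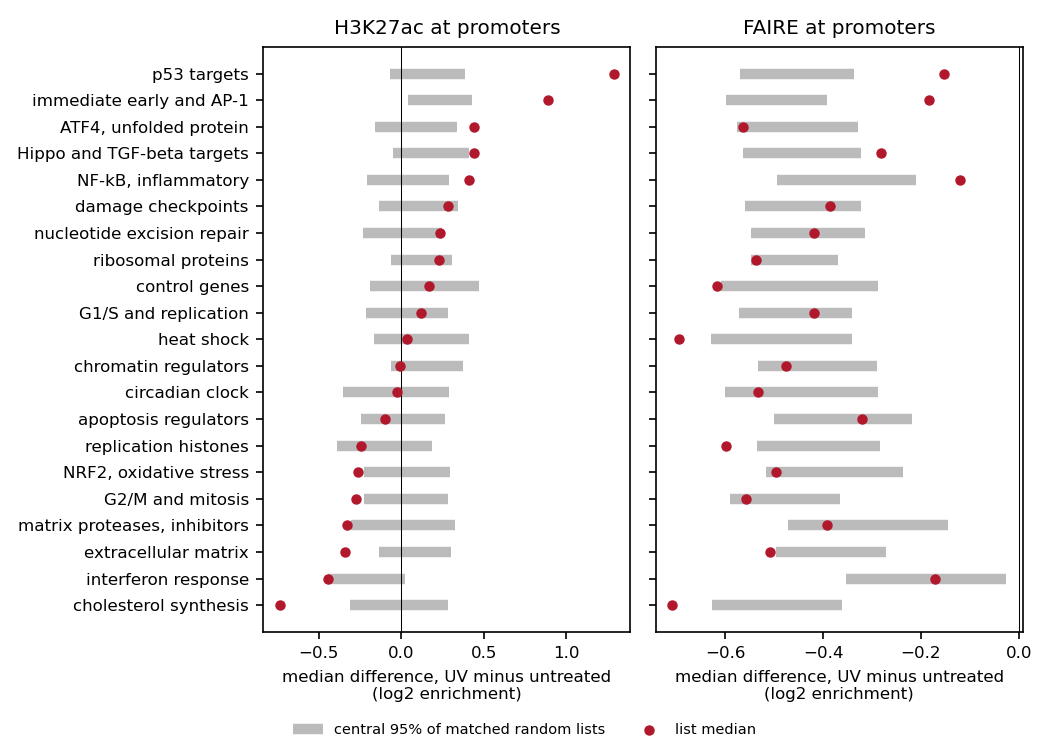
Median difference in log2 enrichment (irradiated minus untreated pool) at the promoters of 21 fixed gene lists for H3K27ac and FAIRE, where each red point is a list's median and each grey bar the central 95% of 10000 random lists matched on enrichment. The p53 targets lay at 1.29 for H3K27ac and at −0.15 for FAIRE, above both bars, and the cholesterol list lay at −0.73 and −0.71, below both.

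Genes that rose in RNA had slightly more promoter H3K27ac after UV, and genes that fell had less than random lists matched on enrichment. The median H3K27ac difference was 0.13 for the 1149 genes higher in RNA, above all 10000 matched random lists (central 95% −0.01 to 0.06), and −0.05 for the 1854 lower ones, below all of them (−0.01 to 0.04). The 11922 genes not called had a median of −0.07, without matching on enrichment, so the lower genes were below matched lists but not below the uncalled genes. For genes changed at least 2-fold the medians were 0.25 and −0.17. Gains of at least 1 were found at 71 of the higher genes (6.18%) and at 59 of the lower ones (3.18%), and losses of at least 1 at 52 (4.53%) and 122 (6.58%). The FAIRE medians were −0.38 for higher and −0.41 for lower genes, against central 95% ranges of −0.41 to −0.37 and −0.41 to −0.38 for random lists. The median of the lower genes lay just below its range, at percentile 2.42, but inside its range, at percentile 7.24, for promoters in the upper 50% by enrichment. For genes changed at least 2-fold the FAIRE medians were −0.27, above all random lists, and −0.43, at percentile 0.02. Among the 10 highest RNA genes the promoter difference in H3K27ac was 1.16 for 1810011O10Rik, 1.22 for Gadd45a and 0.64 for Fos, but 0.03 for Nppb and −0.06 for Lif. Across all 14925 genes, which are not independent replicates, the H3K27ac difference correlated with the RNA log2 fold change at a Pearson r of 0.09 and a Spearman rho of 0.05, and the FAIRE difference at 0.07 and 0.02. Among the 3003 called genes rho was 0.20 and 0.11.

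**Figure D4:**
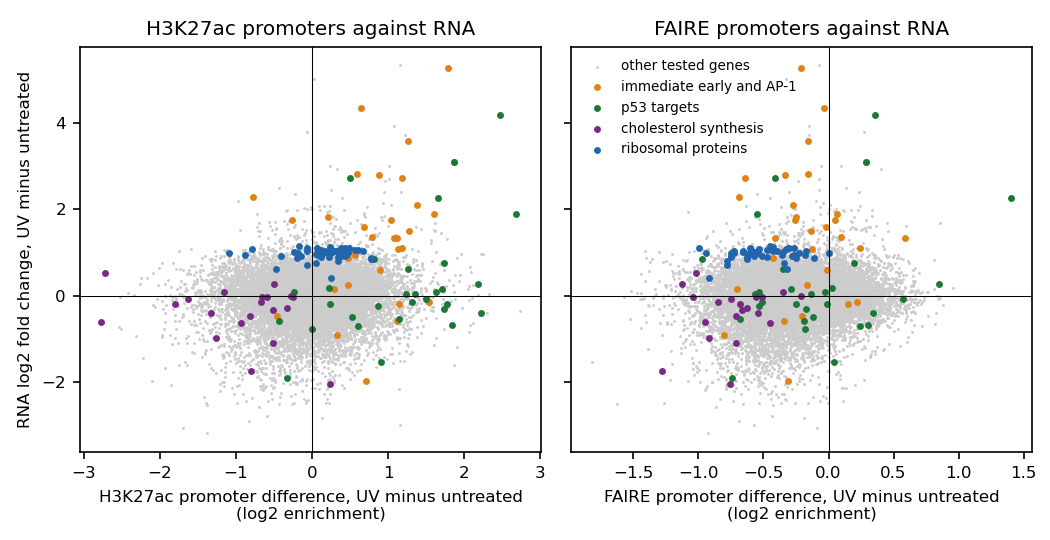
RNA log2 fold change (UV minus untreated) against the promoter difference in log2 enrichment (irradiated minus untreated pool) for H3K27ac and for FAIRE, where each point is 1 of 14925 tested genes and 4 lists are coloured. Pearson's r across genes was 0.09 for H3K27ac and 0.07 for FAIRE, and most p53 targets and immediate early genes lay to the right of 0 for H3K27ac.

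H3K27ac changed in both directions at peaks. Of 90682 H3K27ac peaks 10957 gained and 8922 lost at least 1 in log2 enrichment (12.1% and 9.84%), around a median of 0.03 (95% binomial interval 0.02 to 0.04) that was −0.02 with quantile normalization. With 1 read added in place of 16, 18106 gained and 16849 lost as much. Over 10 classes of H3K27ac peaks by mean enrichment of both pools, the median was 0.33 in the highest. It was −0.08 to 0.06 in the others. Scaled by depth, the irradiated pool held 1.14 times the reads of the untreated pool in these peaks. Whether a shift shared by strong peaks adds to the gains was not tested. In mm9 coordinates, the build named in the submitters' processing notes, the highest gains were on chromosome 17 from 16162324 to 16164077 (37 to 797 reads), on chromosome 10 from 61051635 to 61052891 (47 to 918 reads) and on chromosome 4 from 11109937 to 11111311 (34 to 724 reads). The strongest losses were on chromosome 2 from 131530702 to 131532111 (1247 to 83 reads), on chromosome 17 from 81290197 to 81291026 (624 to 37 reads) and on chromosome 1 from 95081037 to 95081869 (713 to 53 reads). Genes around these sites were not analysed here.

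FAIRE enrichment was lower at most of its peaks, and lowest against untreated cells where H3K27ac was lost. Of 56970 FAIRE peaks 30 gained and 4227 lost at least 1 (0.0527% and 7.42%), around a median of −0.35 (95% binomial interval −0.35 to −0.34). The deposited peak table scales the input for both pools with the depth of the untreated one, and with each pool's own input scale the median was −0.27, with 57 gains and 2923 losses. With quantile normalization the median was 0.02, with 375 gains and 924 losses. With 1 read added in place of 16 it was −0.64, with 875 gains and 17034 losses. The strongest loss lay on chromosome 2 from 131532142 to 131532903 (214 to 18 reads), directly beside the H3K27ac peak with the strongest loss. The next were on chromosome 15 from 8756066 to 8756789 (239 to 22 reads) and from 8766535 to 8767313 (225 to 21 reads). The highest gains were on chromosome 1 from 34242909 to 34243258 (14 to 57 reads), on chromosome X from 94571668 to 94572063 (8 to 42 reads) and on chromosome 7 from 66282818 to 66283186 (13 to 53 reads). Of the FAIRE peaks 66.7% overlapped an H3K27ac peak by at least 1 bp, and 44.3% of the H3K27ac peaks overlapped a FAIRE peak. FAIRE peaks with an overlapping H3K27ac peak had a median difference of −0.45 and those without one −0.18. Over 10 classes of FAIRE peaks by mean enrichment of both pools, the median went from −0.13 in the lowest to −0.69 in the highest. Peaks with and without overlap were not matched on enrichment, so their contrast could not be told apart from one of peak strength. At 3812 FAIRE peaks where the H3K27ac peak lost at least 1 the median was −0.84, at 5084 where it gained at least 1 it was −0.07 (0.02 with each pool's own input scale), and at the other 29076 overlapping peaks it was −0.46. Across the 37972 overlapping peaks, which are not independent replicates, the differences of the 2 assays correlated at a Pearson r of 0.52 and a Spearman rho of 0.46.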

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

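The chromatin pools allow no test, and the RNA p-values rest on 3 libraries per group. No setting gave an opposite call for a gene called in the edgeR fit. With library totals alone 3739 genes were lower. Without a library in turn 585 to 1941 genes were higher and 1139 to 2849 lower, the cause of which was not tested. A log2 fold change of at least 1 left 270 higher and 801 lower genes. Of the 26 lists 10 passed with a preset correlation, 0 with an estimated correlation and 4 with fry. With an estimated correlation the test allows for members that move together between libraries, whereas the preset value is the same for all lists.

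With the replicate number as a block (replicate block), 1276 genes were higher and 2067 lower. The labels do not say that libraries of the same number were handled together. Correlations of the deviations from the group means between libraries of the same number were 0.155, −0.58 and 0.504. Between libraries of different number and group they ran from −0.707 to 0.683, so they do not settle the pairing. By the chi-square, irradiated replicate 1 was closer to untreated replicate 1 (74.56) than to untreated replicates 2 and 3 (101.6 and 108.9). Irradiated replicates 2 and 3 were both closest to untreated replicate 2 (76.31 and 82.49). A batch shared by the replicate 1 libraries was not tested. For chromatin, No paired analysis was possible because the tables hold pooled columns. Alternatives by replicate were not run for the same reason, and the gene length result was not run without annotation.

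FAIRE promoters centred on their median had 10 gains and 76 losses. With quantile normalization they had 12 and 27 around a median of 0.0021, and at 0.58 they had 155 and 3100. FAIRE peaks had 275 gains and 1250 losses when centred, 375 and 924 with quantile normalization around a median of 0.0169, and 447 and 16547 at 0.58. Centring and quantile normalization remove a shift shared by all features by construction. The upper 50% of FAIRE peaks by enrichment had 16 gains, and each pool's own input scale, an alternative chosen after the data were seen, gave 57.

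H3K27ac promoters had a median of 0.0201 with quantile normalization and 0.035 in the upper 50% by enrichment, and 1909 gains and 2641 losses at 0.58. H3K27ac peaks had a median of −0.0194 with quantile normalization, 6925 gains and 5658 losses in the upper 50%, and 21636 and 19453 at 0.58. The medians named here lie close to 0.

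For genes changed at least 2-fold in RNA, FAIRE medians were −0.27 (higher) and −0.43 (lower) and H3K27ac medians 0.25 and −0.17. In the upper 50% by enrichment FAIRE medians were −0.41 and −0.43, and the H3K27ac median of higher genes was 0.19. Spearman's rho with RNA among called genes was 0.11 for FAIRE and 0.20 for H3K27ac, and for H3K27ac in the upper 50% 0.0744. The cause was not tested.

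With each pool's own input scale FAIRE peaks with and without an H3K27ac peak had medians of −0.36 and −0.12. At an overlap of 50% of the shorter peak the medians were −0.43 and −0.28, and the shares were 44.0% of FAIRE and 24.4% of H3K27ac peaks. With the upper 50% of peaks by score they were −0.54 and −0.32, and 76.2% and 55.4%.

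With 1 read added in place of 16, an alternative chosen after the data were seen, FAIRE promoters had 638 gains and 1279 losses and FAIRE peaks 875 and 17034. H3K27ac promoters had 1381 and 3479, and H3K27ac peaks 18106 and 16849. A smaller number of added reads widens differences at features with few reads by construction.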

Other observations

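Further gene sets, defined by symbol patterns after the data were seen, extended the RNA picture. Of 317 tested Zfp genes, which encode zinc finger proteins, 4 rose and 146 fell at a median log2 fold change of −0.55 (camera adjusted p = 1.47e-17, and adjusted p = 0.166 with an estimated correlation). Of 72 respiratory chain genes 54 rose and none fell, at a median of 0.75 (adjusted p = 1.38e-25, and adjusted p = 0.293 with an estimated correlation). Of 26 histone genes outside the fixed list 1 rose and 24 fell, at a median of −1.81 (adjusted p = 6.00e-21, and adjusted p = 0.0511 with an estimated correlation). Of 38 proteasome genes 7 rose and none fell (median 0.39, adjusted p = 2.88e-06, and adjusted p = 0.521 with an estimated correlation), against 9 and 4 at a median of 0.15 with library totals alone and 7 and 3 without irradiated replicate 1. Of 60 translation factor genes 16 rose and 7 fell (median 0.32, adjusted p = 0.00288, and adjusted p = 0.736 with an estimated correlation). With library totals alone 13 rose and 13 fell at a median of 0.08, and without irradiated replicate 1 11 rose and 11 fell at 0.20. Of 73 mitochondrial ribosome genes 22 rose and 6 fell (median 0.17, adjusted p = 0.00805, and adjusted p = 0.753 with an estimated correlation). With library totals alone 13 rose and 21 fell at a median of −0.07, against −0.24 for all tested genes. The sign of their median thus depended on a scaling that lowered the tested genes as a whole. Without irradiated replicate 1 18 rose and 12 fell at 0.03, against 0.05 for all tested genes. None of 81 sensory receptor genes was called (adjusted p = 0.705). Their median of 0.02 was 0.38 without untreated replicate 3, 0.36 without irradiated replicate 1 and −0.30 without irradiated replicate 2. All sensory receptor genes together took 464 CPM in irradiated replicate 1 to 1994 CPM in untreated replicate 3. On principal component 1 of the log2 CPM values (49.1% of the variance) untreated and irradiated libraries overlapped. On component 2 (33.5%) they did not.

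Of the explanations weighed below, those on library scaling, a single library, counting noise and a shared gain were chosen after the result was seen. Among the 10 splits of the RNA libraries into 3 and 3, the real 1 gave 3003 called genes and the highest other gave 0, and 10 splits are too few for a share under 0.05.

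Ribosomal protein transcripts rose while replication histone transcripts fell. The choice of scaling does not account for the ribosomal rise, as the ribosomal median was 0.77 with library totals alone. Nor does a single library, as the lowest ribosomal median over the fits without a library was 0.96. Both scalings measure shares of the counted RNA, so a rise in share while other transcripts fell was not excluded. A candidate explanation is that long-lived transcripts may gain share while RNA synthesis is low after UV. Respiratory chain genes lay 1.30 above Zfp genes in median, which fits that explanation but rests on general knowledge of transcript stability. No half-lives were measured here. Both sets were defined after the data were seen, and a change with gene length was not analysed, so the contrast cannot single out that explanation.

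Promoters of p53 targets gained H3K27ac while their RNA did not rise as a set, although 8 of the 30 genes were called higher and 4 lower. Counting noise alone does not account for the gain. Of all 30 promoters of the list 83.3% had a read ratio interval above 1 (25 above and 1 below). These intervals cover counting error and not the spread between pooled samples, and the share among other promoters was not counted. Nor does a gain shared by strongly acetylated promoters account for it, as the list lay at percentile 100 of matched random lists. The random lists had a median of 0.17, against 1.29 for the p53 targets. Low RNA synthesis may hide new transcripts, but the median RNA log2 fold change of other genes with gaining promoters was 0.0895, which does not decide it.

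FAIRE enrichment at peaks was lower in the irradiated pool. The untreated input scale in the peak table is not the whole cause, as the median was −0.27 with each pool's own scale. A lower yield of open DNA over all sites may be the cause, and this could not be told apart from a loss of openness. Among 10 classes of peaks by untreated enrichment, the lowest class had a median of 0.17. That class is chosen for low untreated reads, and ranked by both pools the highest median was −0.05.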
